A study of Mus musculus with 21 samples.

How the data were processed

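PolyA RNA sequencing of 21 mouse samples was examined, 12 from Neuro2a cultures and 9 from NeuN-sorted nuclei of mouse cortex. Per the labels' protocols, Neuro2a cells received 750 ng each of the guide RNA and the sadCas9-VP64 plasmids, and control cultures the latter alone. Mice on a C57BL/6J background received 500 nL of rAAV with guide RNA and sadCas9-VP64 in equal parts into the medial prefrontal cortex and were used 4 weeks later, and nuclei were taken from 200 mg of cortex. Among the mouse samples, the labels give a treatment for the Het CRISPRa group alone and do not say whether WT and Het mice received any injection.

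The submitters' processing notes name STAR 2.7.8a, featureCounts, DESeq2 1.44 and R 4.4 with the genome builds mm39 and GRCm39, and give no role or order for them. Per the file headers and file names, the deposited tables of levels hold CPM, 31553 features for Neuro2a and 39008 for the mouse nuclei, transgene features included, and each library sums to 1e+06. The tool that made the CPM, the strandedness, the treatment of reads with several alignments and the annotation release are not stated in them. The authors' deposited DESeq2 tables give a log2 fold change with its standard error for each of the 4 comparisons. The same deposited tables hold the authors' p-value and adjusted p-value. The authors' values were used only for counts and genes set beside those computed here. Where their sign was coded as WT against Het it was turned to Het minus WT.

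The value of 1 read in each library was taken as the most frequent CPM value above 0. The inverse of that value was taken as the depth, 15.5 to 21 M reads (M, 1e+06) in Neuro2a and 15.5 to 20.1 M in the mouse libraries. At that scale 79.9 to 82.4% of the mouse and 70.8 to 73.2% of the Neuro2a values above 0 lay within 0.01 of a whole number of reads. The tables thus hold estimated rather than whole reads, and tests that need whole reads (edgeR, DESeq2) were not run. Where a feature was listed at 0, 3 reads of the library were taken as the floor, and floors cover counting error only.

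Samples were grouped by the titles, genotype and treatment in the labels. The Neuro2a library names give a library set (7 or 8), with replicates 1 to 3 in set 7 and 4 to 6 in set 8. After subtracting group means, the Neuro2a libraries of the same replicate number had correlations across genes of 0.305 to 0.499, all above 0.1, and were treated as pairs in an alternative with a replicate block, while within a library set these correlations were -0.0708 to 0.0229, so that the shared part follows the library set. The first principal components held 45.3 and 20.8% of the variance in Neuro2a and 33.9 and 14.5% in the mouse libraries.

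Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) on log2(CPM + 0.5). Genes with at least 0.5 CPM in at least 6 Neuro2a libraries or 3 mouse libraries were tested, which left 14398 and 18967 genes. The 2 transgene features were kept out. All 9 mouse libraries were fitted together, and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison with 0.05 as the threshold. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for exact permutation tests (two-sided, on mean CPM) and plots. The SE is that of the limma fit and the SD is between libraries.

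Before the data were examined, 28 gene lists, the model, the filter, the threshold, the alternatives and the rule for named genes were fixed, except where an alternative or test is said to have been added later. The lists were the sodium, potassium and calcium channels, genes around Scn2a, axon initial segment proteins, excitatory postsynapse, presynaptic release, immediate early genes, autism and neurodevelopmental disorder genes, interferon response, p53 targets, unfolded protein response, heat shock, cell cycle, neuronal differentiation, mitochondrially encoded mRNAs, ribosomal protein mRNAs, nuclear retained RNAs, markers of excitatory, inhibitory, striatal, and hippocampal and thalamic neurons, of astrocytes, oligodendrocytes, their precursors, microglia and vascular cells, and a list of 5 sex-linked genes used only to look at the sex of the mice. Lists with at least 3 measured members (27 in each comparison) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives to that were camera with a correlation estimated from the data and fry, which asks whether a list's genes move one way and compares them with no other genes.

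The rule named Scn2a, every tested sodium channel and gene around Scn2a, and up to 4 members with the smallest p of each list past the camera threshold. It also named the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 2 CPM, separate groups and a symbol that is not a predicted or clone name. Where no gene met this, it named the 5 per direction with the smallest unadjusted p, given as values that did not pass. The values of some genes that the rule named are not reported.

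Alternatives were pseudocounts of 0.1 and 2, no filter, a filter at 2 CPM, median-of-ratios and quantile scaling, robust eBayes, the replicate block, the library set as a covariate, each library set alone, the run of mouse library numbers as a covariate, only the 6 libraries compared, each library left out in turn, and an adjusted p of 0.1 for overlaps. Added after seeing the data were the mitochondrial mean and the number of genes at 1 read as covariates in the mouse fits. The fit was tested on simulated data with 50 changed genes at each of 4 sizes. Gene classes came from GENCODE M21 on GRCm38, by gene identifier (94.6% of Neuro2a and 90.4% of mouse genes tested were matched). The order of neighbours came from the RefSeq protein-coding genes on GRCm38, by symbol. Because the authors' builds differ from GRCm38, no coordinates are given.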

Results

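RNA levels were measured by polyA RNA sequencing in 21 mouse samples. A first experiment used Neuro2a, a mouse neuroblastoma line, with 6 cultures given a guide RNA plasmid together with sadCas9-VP64 (CRISPRa) and 6 given sadCas9-VP64 alone (VP64 only). In CRISPR activation, a catalytically dead Cas9 fused to the transcriptional activator VP64 is brought to a promoter by a guide RNA. The Neuro2a library names fall into library set 7 (replicates 1 to 3 of both groups) and library set 8 (replicates 4 to 6). A second experiment used NeuN-sorted neuronal nuclei from cortex, with 3 wild-type mice (WT), 3 Scn2a+/- mice (Het) and 3 Scn2a+/- mice injected with rAAV carrying the activator and an Scn2a guide RNA (Het CRISPRa). The estimated depth, read from the value that 1 read takes in each library, was 15.5 to 21 M reads in Neuro2a and 15.5 to 20.1 M in the mouse libraries. Levels are counts per M reads (CPM; M, 1e+06) with the SD between libraries. Changes are differences of log2(CPM + 0.5) with the SE of the limma fit, a scale that understates changes of genes with low CPM. Adjusted p-values are limma with Benjamini-Hochberg adjustment over all genes tested. The p-values measure the spread between these samples, which may be technical in part.

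The comparison of CRISPRa with VP64 only in Neuro2a cells asks what adding the guide RNA plasmid did to Scn2a and to other transcripts. Scn2a (ENSMUSG00000075318), which encodes the voltage-gated sodium channel Nav1.2, rose from 3.09 ± 0.23 CPM (SD, n = 6) to 4.61 ± 0.50 CPM (n = 6), a ratio of 1.49. Its log2 change was 0.50 ± 0.10 (SE; adjusted p = 0.00531), and all 6 CRISPRa libraries lay above all 6 VP64-only libraries (exact two-sided permutation test, p = 0.00216, the smallest this design can give). Between 47 and 96 reads per library stood behind these values. Within library set 7 Scn2a was 4.81 ± 0.46 against 3.16 ± 0.31 CPM, and within set 8 it was 4.4 ± 0.54 against 3.02 ± 0.15 CPM (n = 3 each; exact permutation p = 0.1 in both, the smallest possible for 3 against 3). With set 7 alone the change passed the test (0.54, adjusted p = 0.0122), and with set 8 alone it did not (0.47, adjusted p = 0.0528). The change in set 8 minus that in set 7 was -0.06 and did not pass its own test (adjusted p = 0.871). With the replicate block, which pairs libraries of the same number, the adjusted p was 0.00782, and over all 23 alternatives it ran from 0.00108 to 0.0528. In the authors' deposited table the Scn2a change was 0.52 ± 0.14 (SE; adjusted p = 0.00285).

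**Figure D1:**
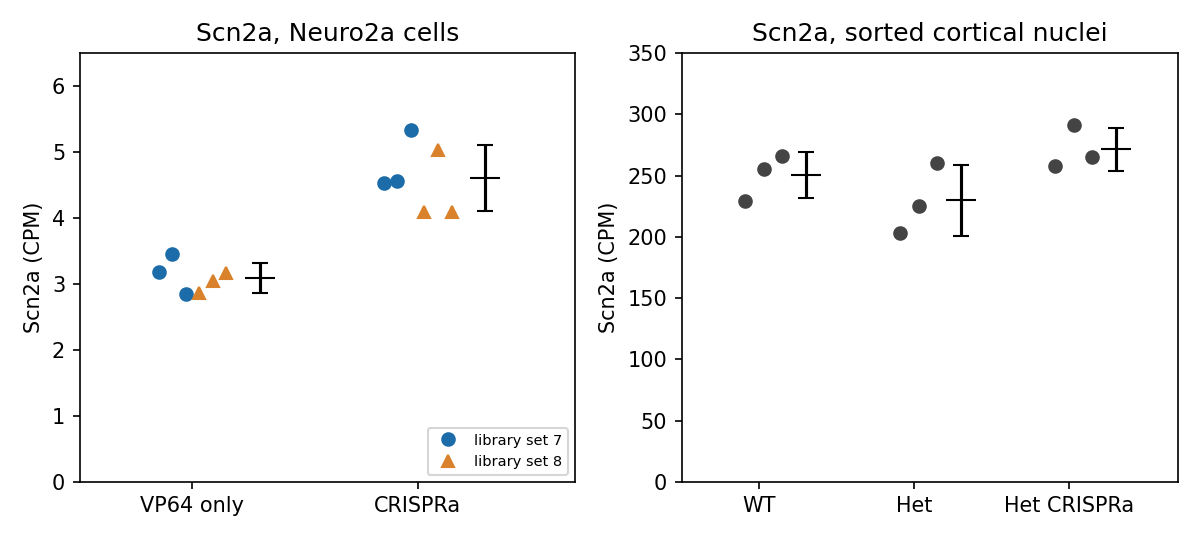
Scn2a level in CPM (vertical axes, starting at 0) for each library, by group; the horizontal mark is the group mean and the bars are the SD. In Neuro2a cells (left; circles are library set 7 and triangles set 8) the means were 3.09 and 4.61 CPM with no overlap, and in sorted cortical nuclei (right) the groups overlapped at 250.3, 229.7 and 271.3 CPM.

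Scn2a was the only member of the list of voltage-gated sodium channel subunits to pass the test (1 rose and 0 fell of 8 measured members, and 1 rose adjusted over the list alone; camera adjusted p for the list did not pass). Values of members that did not pass were -0.24 for Scn3b, -0.19 for Scn3a, 0.17 for Scn9a, 0.10 for Scn8a and 0.09 for Scn4a. Among the 11 measured genes around Scn2a on chromosome 2, Ifih1 alone passed the test (1 rose and 0 fell, over all genes and adjusted over the list alone; the list did not pass camera). Ifih1 encodes the double-stranded RNA sensor MDA5, and belongs to the interferon list as well, whose median was also 1.02. It rose from 53.2 ± 14.5 to 106 ± 15.8 CPM, a log2 change of 1.02 ± 0.16 (n = 6 and 6; adjusted p = 0.0015). The neighbours nearest in annotated order, Scn3a and Csrnp3, gave values of -0.19 and -0.08. Galnt3 (-0.29), Cobll1 (0.23), Ttc21b (-0.20), Fign (-0.32), Grb14 (-0.17), B3galt1 (-0.11), Gca (-0.02) and Scn9a (0.17) did not pass either. With the replicate block Fign, Galnt3 and Ttc21b passed. These genes also passed as falls in set 7 alone (-0.58, -0.43 and -0.24), and none of them passed in set 8 alone (-0.05, -0.15 and -0.16). Scn9a passed with the library set as a covariate and, with Scn8a, in set 7 alone, both as rises. Of the 11 genes around Scn2a, 2 rose and 3 fell in set 7 alone, and 1 rose and 0 fell in set 8 alone.

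Across the transcriptome, 2166 of 14398 genes tested passed the test, with 1443 higher and 723 lower in CRISPRa cultures. At least a 2-fold change was seen in 144 of the genes that rose and 19 of those that fell. In 1260 genes (8.75%, where chance gives a share of 0.00216) the 6 CRISPRa libraries did not overlap the 6 VP64-only libraries, and 1221 of these were among the genes that passed. The split by direction depended on the scaling of the libraries, with 1062 higher and 1104 lower under median-of-ratios scaling (2166 in all) and 1058 higher and 1015 lower under quantile scaling. The replicate block gave 4513 genes (2865 higher, 1648 lower), and it kept 2160 of the 2166. Fitted separately, the sets shared 2368 genes past the threshold, 2160 in the same direction and 208 in opposed directions, and across all 14398 genes the changes in the sets had a Pearson correlation of 0.509 (across genes, which are not independent replicates). The authors' deposited table held 2746 genes past an adjusted p of 0.05 (1376 higher, 1370 lower), of which 1941 also passed here, all in the same direction.

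Genes of the interferon response and antigen presentation made up the list with the strongest camera test at the preset correlation, though not with an estimated correlation. Of its 29 measured members 26 rose and 1 fell, with 27 rising and 1 falling when adjusted over the list alone. The median change was 1.02, with 0.71 in library set 7 and 1.29 in set 8. The camera test of the list gave an adjusted p of 4.5e-13, and an adjusted p = 0.359 with an estimated correlation. Cxcl10, a chemokine, rose from 70.2 ± 12.9 to 249 ± 78.7 CPM, a log2 change of 1.78 ± 0.19 (n = 6 and 6; adjusted p = 0.000142), and Ifit2, which binds foreign RNA, rose from 77.1 ± 21.7 to 189 ± 24.3 CPM (1.33 ± 0.16). Isg15, a ubiquitin-like modifier (1.02 ± 0.15), and Oasl2 (0.70 ± 0.07) also rose. Ifi27 was the member that fell (-0.55, adjusted p = 0.0335), and H2-K1 (0.56) and Ifi27l2a (0.79) did not pass in this fit of both sets. Fitted alone, set 7 had 27 of the 29 members rising and 1 falling, and set 8 had 28 rising and 1 falling. The change of this list was larger in set 8 than in set 7 (median difference 0.37, camera adjusted p = 2.6e-13, and adjusted p = 0.280 with an estimated correlation). A further 8 lists passed this camera test of the difference between the sets. The median of set 8 minus set 7 was above 0 for the autism genes (0.23), ribosomal protein mRNAs (0.10), unfolded protein response (0.13), calcium channels (0.23) and genes around Scn2a (0.27), and below 0 for the immediate early genes (-0.30), cell cycle (-0.25) and mitochondrially encoded mRNAs (-0.40). With an estimated correlation none of the 27 lists passed.

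The largest rise of all named genes was that of Zbp1, a sensor of Z-form nucleic acid, from 4.23 ± 3.99 to 43.5 ± 24.2 CPM, a log2 change of 3.64 ± 0.64 (n = 6 and 6; adjusted p = 0.0026). Oas3, which makes the activator of RNase L, rose from 39.4 ± 25.6 to 166 ± 23.6 CPM (2.34 ± 0.37). The other genes among the 10 largest rises were Ifi44l (3.47 ± 0.47), Ifi47 (3.0 ± 0.65), 9930111J21Rik2 (2.64 ± 0.57), Gbp2 (2.56 ± 0.48), Csprs (2.51 ± 0.43), Sp110 (2.46 ± 0.49), Gbp2b (2.35 ± 0.46) and Gbp9 (2.33 ± 0.51), of which the Gbp genes encode guanylate-binding GTPases.

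The transgene transcripts moved with both the groups and the library sets. The sadCas9-VP64 transcript was at 1977 ± 256 CPM in CRISPRa and 2549.6 ± 83.7 CPM in VP64-only cultures of set 7, and at 599.8 ± 34.3 and 349 ± 27.5 CPM in those of set 8 (n = 3 each; exact permutation p = 0.1 within each set, the smallest possible). Over both sets its means were 1288 and 1449 CPM (n = 6 each; exact permutation p = 0.714). The mCherry-puromycin transcript was at 5296 ± 599.6 CPM in set 7 and 1727 ± 181 CPM in set 8 of the CRISPRa cultures, and listed at 0 in the 6 VP64-only cultures.

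**Figure D2:**
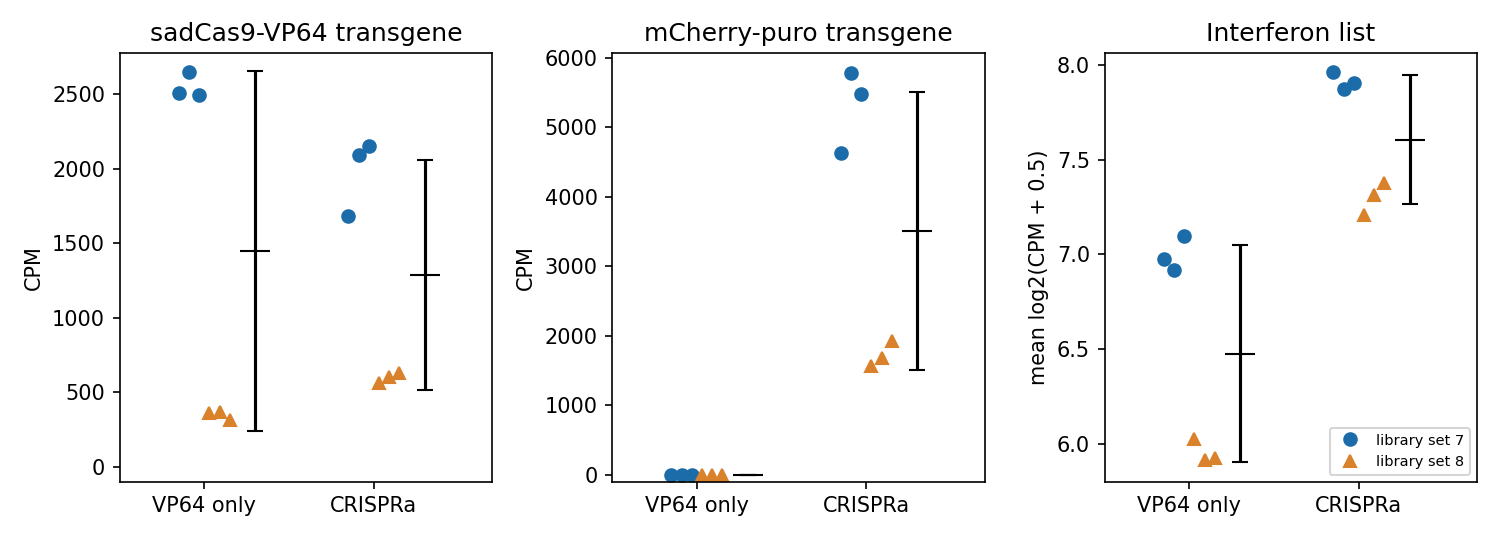
Transgene transcripts in CPM (left and middle) and the mean log2(CPM + 0.5) of the interferon list (right, an axis that does not start at 0) for each Neuro2a library; circles are library set 7, triangles set 8, the horizontal mark is the mean and the bars are the SD. The interferon list means were 7.91 (set 7) and 7.30 (set 8) in CRISPRa and 7.0 and 5.96 in VP64-only cultures, so that both groups were higher in set 7.

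The 10 largest falls included enzymes and mitochondrial proteins. Car12, a carbonic anhydrase, fell from 175 ± 12.7 to 79.0 ± 5.27 CPM, a log2 change of -1.14 ± 0.06 (n = 6 and 6; adjusted p = 4.0e-07, the smallest of all genes). Bnip3, a mitophagy receptor, fell from 218 ± 77.4 to 69.7 ± 13.5 CPM (-1.58 ± 0.21). Pdk1, the kinase that turns off pyruvate dehydrogenase, fell from 51.4 ± 13.4 to 20.4 ± 2.21 CPM (-1.28 ± 0.15), and Fam162a, a mitochondrial protein, fell from 120.4 ± 32.1 to 56.2 ± 9.33 CPM (-1.07 ± 0.16). The others were Selenbp1 (-1.64 ± 0.24), Cyp2s1 (-1.59 ± 0.21), the neurexophilin Nxph4 (-1.45 ± 0.26), the matrix protein Matn3 (-1.05 ± 0.16), the growth-factor binding protein Igfbp5 (-1.04 ± 0.19) and the cytochrome oxidase subunit Cox4i2 (-1.0 ± 0.14).

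Immediate early genes and mitochondrially encoded mRNAs were higher in CRISPRa cultures. Of 18 measured immediate early genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.46 (0.61 in set 7 and 0.28 in set 8). The camera adjusted p was 6.8e-07, and adjusted p = 0.257 with an estimated correlation. The phosphatase gene Dusp1 rose by 0.98 ± 0.12, and the transcription factor genes Jun (0.62 ± 0.07), Junb (0.56 ± 0.07) and Nr4a1 (0.45 ± 0.07) rose as well. Of 13 measured mitochondrially encoded mRNAs 10 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.53 (0.72 in set 7 and 0.34 in set 8). The camera adjusted p was 1.5e-06, and adjusted p = 0.257 with an estimated correlation. Examples are mt-Nd4 (0.80 ± 0.12), mt-Cytb (0.73 ± 0.11), mt-Co1 (0.62 ± 0.11) and mt-Nd2 (0.49 ± 0.08). Genes with a symbol starting with mt-, of which the listed mRNAs are a part, made up 1.33 ± 0.146% of the CRISPRa libraries and 0.933 ± 0.0915% of the VP64-only libraries.

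A few lists had lower medians in CRISPRa cultures. Of 24 measured autism and neurodevelopmental disorder genes, 9 fell and 1 (Scn2a itself) rose, with 11 and 1 when adjusted over the list alone. The median was -0.19 (-0.26 in set 7 and -0.05 in set 8, which did not pass by itself), with a camera adjusted p of 7.2e-06, and adjusted p = 0.359 with an estimated correlation. The transcription factor genes Foxp1 (-0.31 ± 0.05) and Tcf4 (-0.23 ± 0.04) and the chromatin remodeller gene Chd2 (-0.47 ± 0.10) fell. None of the 28 ribosomal protein mRNAs passed the limma test, although all 28 values lay below 0, with a median of -0.16 (-0.21 in set 7 and -0.13 in set 8). The camera adjusted p of that list was 7.2e-06, and adjusted p = 0.778 with an estimated correlation, and with quantile scaling the median was -0.08 and did not pass. Rpl3 (-0.40), Rpl10 (-0.27) and Rpl11 (-0.25) did not pass in the fit without a block but did with the replicate block, with which 19 of the 28 members fell. Of 22 cell cycle genes 3 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.11, a camera adjusted p of 0.00951, and adjusted p = 0.830 with an estimated correlation. The median of this list was 0.08 in set 7, -0.20 in set 8 and between -0.19 and 0.01 when single libraries were left out. Its call was lost with fry, with quantile scaling, in set 7 alone and without VP64-only replicate 3 (-0.04) or CRISPRa replicates 4 (-0.01), 5 (0.01) or 6 (-0.01). Top2a (-0.53 ± 0.06), Aurkb (-0.49 ± 0.09) and Cdk1 (-0.27 ± 0.06) fell, and the cyclin gene Ccnd1 rose (0.57 ± 0.07). Of 4 measured astrocyte markers Ndrg2 (-0.69 ± 0.12) and Aldoc (-0.79 ± 0.21) fell, with 0 rising and 3 falling adjusted over the list alone, while Fgfr3 (-0.24) and Sox9 (0.18) did not pass. Sox9 passed as a rise, against the direction of the list, with the replicate block, with the library set as a covariate and in set 7 alone (0.23), and Fgfr3 passed as a fall with the library set as a covariate and in set 7 alone (-0.48). That list had a median of -0.47 (-0.53 in set 7 and -0.40 in set 8), a camera adjusted p of 0.032 and adjusted p = 0.257 with an estimated correlation, and its call was lost with the replicate block, with the library set as a covariate, with quantile scaling, with no filter (median -0.0025), within each set, and without VP64-only replicate 3 (-0.42) or CRISPRa replicate 3 (-0.43). Over the alternatives the adjusted p of Aldoc ran from 1.7e-05 to 0.0504, the latter without VP64-only replicate 1.

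**Figure D3:**
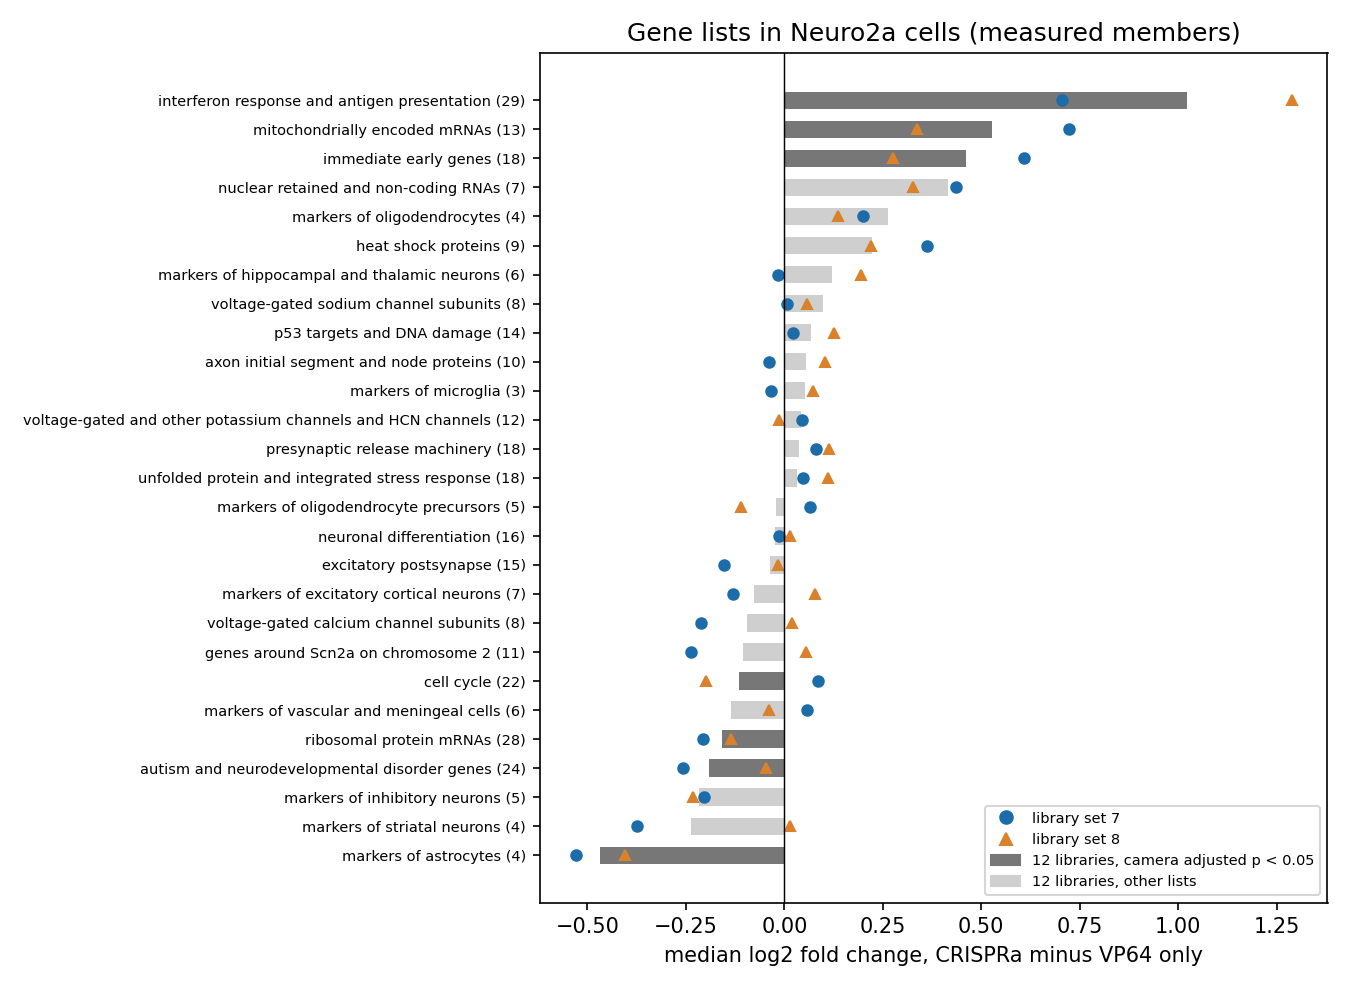
Median log2 fold change (horizontal axis, CRISPRa minus VP64 only) of the measured members of 27 gene lists in Neuro2a cells, with the number of members in brackets; bars are all 12 libraries, dark where the camera adjusted p was under 0.05, circles are library set 7 and triangles set 8. The interferon list had the highest median (1.02) and the astrocyte markers the lowest (-0.47); the cell cycle list was above 0 in set 7 (0.08) and below 0 in set 8 (-0.20).

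The other 20 lists did not pass the camera test in Neuro2a cells (adjusted p 0.0828 to 0.953), with medians from -0.24 to 0.41. They were potassium channels, calcium channels, axon initial segment proteins, excitatory postsynapse, presynaptic release, sodium channels, genes around Scn2a, p53 targets, the unfolded protein response, heat shock proteins, neuronal differentiation, nuclear retained RNAs, and the markers of excitatory, inhibitory, striatal, hippocampal and thalamic neurons, oligodendrocytes, their precursors, microglia and vascular cells. The heat shock proteins (median 0.22) passed as a rise with the library set as a covariate, in set 8 alone (0.22), with quantile scaling (0.39) and without CRISPRa replicate 1 (0.26). With fry, which compares a list with no other genes, 8 of these lists passed, those of heat shock proteins, sodium channels, p53 targets, neuronal differentiation, nuclear retained RNAs and the markers of inhibitory and striatal neurons and oligodendrocytes. In simulated data with 6 libraries against 6, 84% of genes changed 2-fold and 60% of those changed 1.5-fold were recovered.

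The comparison of Het with WT asks how the loss of an Scn2a copy changed the transcripts of sorted cortical nuclei. Scn2a was at 229.7 ± 28.7 CPM in Het and 250.3 ± 18.8 CPM in WT (SD, n = 3 each), a difference of -0.13 ± 0.11 that did not pass (adjusted p = 0.875; exact two-sided permutation p = 0.4). It was -0.04 without Het replicate 1, -0.08 without WT replicate 3, -0.19 without WT replicate 1 and -0.22 without Het replicate 3, and, with covariates chosen after the results were seen, -0.29 with the number of genes at 1 read and -0.03 with the mean of the mitochondrially encoded mRNAs. None of these passed. The ratio of the Het mean to the WT mean was 0.918. Over all 18 alternatives the difference ran from -0.29 to -0.03, well short of a 2-fold fall. Gene-level values do not tell the alleles apart. Egr1, an activity-regulated transcription factor gene, had the value with the smallest unadjusted p of the genes that the rule named, at 49.8 ± 6.80 CPM in Het and 82.9 ± 8.60 CPM in WT (-0.73 ± 0.13; adjusted p = 0.333). By limma 0 of 18967 genes passed, and 951 had an unadjusted p under 0.05 (5.01%, where chance gives a share of 0.05). The groups did not overlap in 2025 genes (10.7%, where chance gives 10%). Without Het replicate 1, 1 gene passed, and with the replicate block 2 did. The authors' deposited table held 15 genes past an adjusted p of 0.05, 11 higher and 4 lower in Het, among them Egr1 (-0.68, adjusted p = 0.0217).

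Between Het and WT 6 gene lists passed the camera test, each with an adjusted p = 0.874 with an estimated correlation and with 0 members passing the test over all genes. The mitochondrially encoded mRNAs had a median of 0.36 (11 of 13 values above 0; adjusted p = 3.8e-06), with 1 rising adjusted over the list alone, and mt-Atp6 (0.74) and mt-Co2 (0.61) as examples. All genes with a symbol starting with mt- made up 1.88% of the library of Het replicate 1 and 0.733 to 1.41% of the other 8 libraries. Het replicate 1 also had the highest mean of the mitochondrial list (9.19) and of the ribosomal protein mRNAs (5.39). The samples are sorted nuclei, so carry-over of mitochondrial RNA into a preparation cannot be told apart from a change of expression. Without Het replicate 1 the list median was 0.11 and the call was lost, while without WT replicate 3 it was 0.13 and without Het replicate 3 it was 0.64. The presynaptic release genes had a median of -0.14 (19 of 23 below 0; adjusted p = 0.0188; 0 adjusted over the list alone), with the calcium sensor Syt1 at -0.30, the complexin Cplx1 at -0.47, the active zone protein Bsn at -0.24 and Unc13a at 0.24. The immediate early genes had a median of -0.19 (13 of 19 below 0; adjusted p = 0.0188; 1 fell adjusted over the list alone), with Fos at -0.60, Btg2 at -0.55 and Dusp6 at -0.39. The markers of inhibitory neurons had a median of -0.22 (18 of 19 below 0; adjusted p = 0.0188; 0 adjusted over the list alone), with the GABA transporter Slc32a1 at -0.53, Erbb4 at -0.40, Reln at -0.28 and Dlx6os1 at -0.51. The ribosomal protein mRNAs had a median of 0.12 (23 of 28 above 0; adjusted p = 0.0188; 0 adjusted over the list alone), with Rps24 at -0.39, Rpl19 at 0.27, Rps2 at 0.19 and Rpl3 at 0.17. The potassium channels had a median of -0.12 (22 of 29 below 0; adjusted p = 0.0476; 0 adjusted over the list alone), with Kcnd2 at -0.52, Kcnh5 at 0.67, Kcnq5 at -0.27 and Kcna2 at 0.26.

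The 3 Het libraries listed 25410 to 25801 genes above 0 CPM and the 3 WT libraries 28109 to 28272, and with the number of genes at 1 read as a covariate the presynaptic (median -0.09), immediate early gene (-0.10) and potassium channel (0.02) calls were lost, while the medians of the inhibitory markers (-0.98), mitochondrially encoded mRNAs (0.74) and ribosomal protein mRNAs (0.43) moved further from 0 and their calls were kept. Genes at 1 read did not overlap between the groups (1266 to 2045 in Het, 2886 to 3143 in WT), so the medians with that covariate are extrapolated. Single libraries decided several of the list calls. The presynaptic call was lost without Het replicate 1 (median -0.13) or Het replicate 3 (-0.15), the immediate early gene call without Het replicate 3 (-0.12), and the inhibitory call without WT replicate 1 (-0.25), Het replicate 1 (-0.11) or Het replicate 2 (-0.21). Without Het replicate 3 the inhibitory median was -0.38, and the immediate early gene median without WT replicate 3 was -0.10, with both calls kept. The ribosomal median turned to -0.05 without Het replicate 1 and -0.03 without WT replicate 3, and was 0.21 without WT replicate 1 and 0.22 without Het replicate 3, and the potassium channel call was kept only without WT replicate 2 among the 6 fits that left out a library (medians of the others -0.16 without WT replicate 1, -0.12 without WT replicate 3, -0.11, -0.15 and -0.21 without Het replicates 1, 2 and 3). The other 21 lists did not pass (adjusted p 0.0726 to 0.949), with medians from -0.64 for striatal markers (11 of 12 values below 0; list means from 3.72 in Het replicate 1 to 6.07 in WT replicate 3) to 0.04. Some of these passed in alternatives. The striatal markers did with median-of-ratios (-0.59) and quantile (-0.56) scaling, the replicate block, the library-number run and genes at 1 read (-1.54), and without WT replicates 1 (-0.88) or 2 (-0.76) or Het replicate 3 (-1.16). The heat shock proteins did with quantile scaling (-0.12), the replicate block and the mitochondrial mean (-0.20), and without WT replicate 3 (-0.23) or Het replicate 2 (-0.26). The sodium channels did with quantile scaling (-0.14) and without WT replicate 1 (-0.25) or Het replicate 3 (-0.22), the autism genes with quantile scaling (-0.08), the interferon list without Het replicate 2 (0.13) and the hippocampal and thalamic markers without Het replicate 3 (-0.39). The genes that the rule named by smallest unadjusted p did not pass and had values, above 0, of 1.00 for Mir99ahg, 0.92 for Etv4, 0.71 for the ribosomal protein gene Rpl15, 0.65 for the adhesion molecule gene Igsf11 and 0.62 for the endolysosomal channel gene Tpcn2. Below 0 they were, beside Egr1, Islr (-0.96), Rgmb (-0.55), the cyclin gene Ccnd2 (-0.47) and Rn18s-rs5 (-0.41). Among the other sodium channels and the neighbours of Scn2a 0 passed, with values that included -0.99 for Scn4b, 0.46 for Grb14 and -0.31 for Kcnh7.

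The comparison of Het CRISPRa with Het asks how injected mice differed from mice of the same genotype. The virus was injected into the medial prefrontal cortex and the labels do not say which part of the cortex was taken, so the values average over nuclei with and without the vector in a share that was not measured. Scn2a was at 271.3 ± 17.7 CPM in Het CRISPRa and 229.7 ± 28.7 CPM in Het (SD, n = 3 each), a ratio of 1.18. The log2 difference of 0.25 ± 0.11 did not pass (adjusted p = 0.810; exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). It was 0.16 without Het replicate 1, 0.34 without Het replicate 3, 0.03 with the mitochondrial mean as a covariate and 0.37 with genes at 1 read, and none of these passed. The injected mice also held the transgene transcripts, with sadCas9-VP64 at 5.21 ± 1.67 CPM and mCherry-puromycin at 1.63 ± 0.20 CPM (66 to 124 and 26 to 32 reads per library). In the 6 other mice they were listed at 0, where 3 reads would be 0.149 to 0.193 CPM per library, a floor that covers counting error only.

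By limma 8 of 18967 genes passed between Het CRISPRa and Het, 1 higher and 7 lower. An unadjusted p under 0.05 was found for 996 genes (5.25%, where chance gives a share of 0.05). The groups did not overlap in 1893 genes (9.98%, where chance gives 10%). The symbols of the 8 genes that passed fall outside the rule for named genes, and each was chosen after its values were seen. Gm3020 (ENSMUSG00000079402), a predicted gene, was at 3.18, 1.98 and 2.07 CPM in the Het CRISPRa libraries and listed at 0 in the 6 others (adjusted p = 0.0121). A230103L15Rik fell from 147 ± 46.3 to 42.4 ± 7.64 CPM (-1.75 ± 0.23), with 54.5 to 93.8 CPM in WT, and Gm37999 fell from 16.9 ± 4.38 to 3.25 ± 0.986 CPM (-2.22 ± 0.28). Gm48700 fell from 35.7 ± 2.87 to 14.7 ± 2.38 CPM (-1.26 ± 0.15; adjusted p = 0.0128). Gm42876 (-1.75 ± 0.24), Gm49594 (-1.67 ± 0.25), Gm44291 (-1.62 ± 0.24) and Gm19817 (-1.45 ± 0.21) fell as well. In the annotation 6 of these 7 are loci of the class TEC, which awaits experimental evidence, and Gm49594 is a processed pseudogene. Leaving out single libraries gave 38 genes without Het replicate 3, 5 without Het replicate 1, 1 without CRISPRa replicate 1, and 0 without Het replicate 2, CRISPRa replicate 2 or CRISPRa replicate 3. The replicate block gave 31 genes, and the authors' deposited table held 74 (10 higher, 64 lower), which included all 8.

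The mitochondrially encoded mRNAs were the list with the strongest camera test at the preset correlation between Het CRISPRa and Het. All 13 values were below 0, with a median of -0.77 (camera adjusted p = 4.5e-16, and adjusted p = 0.667 with an estimated correlation). None passed over all genes, and 10 fell adjusted over the list alone. Without Het replicate 1 the median was -0.51, and the call was kept. Without Het replicate 3 mt-Atp6 (-1.19), mt-Nd4 (-1.09) and mt-Cytb (-1.02) passed over all genes. Examples are mt-Atp6 (-0.94), mt-Atp8 (-0.88), mt-Nd4 (-0.79) and mt-Cytb (-0.74). All genes with a symbol starting with mt- made up 0.784 ± 0.0486% of the Het CRISPRa, 1.40 ± 0.495% of the Het and 1.02 ± 0.229% of the WT libraries. Carry-over of such RNA into the sorted nuclei was not measured, so it cannot be told apart from a change of expression. The ribosomal protein mRNAs had a median of -0.21 (25 of 28 below 0, 0 passing over all genes or adjusted over the list alone; adjusted p = 6.6e-07, and adjusted p = 0.693 with an estimated correlation), with Rps6 at -0.37 and Rpl19 at -0.50. The immediate early genes had a median of -0.11 (14 of 19 below 0, 0 passing over all genes or adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.693 with an estimated correlation), with Arc at -0.38, Ier2 at -0.49, Ier5 at -0.26 and Dusp1 at -0.25. Without Het replicate 1 the calls of the ribosomal (median -0.09) and immediate early gene (-0.08) lists were lost, the latter also without Het replicate 2 (-0.18), CRISPRa replicate 1 (-0.16) or CRISPRa replicate 2 (-0.08). Without Het replicate 3 the ribosomal median was -0.34 and that of the immediate early genes -0.27, the latter was -0.17 without CRISPRa replicate 3, and these calls were kept. With genes at 1 read as a covariate the ribosomal median was -0.48 and the call was kept, and that of the immediate early genes was -0.20 and the call was lost. With the mean of the mitochondrially encoded mRNAs as a covariate the ribosomal median turned to 0.15 and that of the immediate early genes to 0.08. The other 24 lists did not pass (adjusted p 0.0609 to 0.953; medians -0.26 to 0.35), among them the interferon list with a median of 0.22. Some of these passed in alternatives. The interferon list did with a pseudocount of 2 (0.15), no filter (0.26), quantile scaling (0.20), the replicate block, the library-number run and the mitochondrial mean (0.30), and without Het replicate 1 (0.26) or CRISPRa replicate 2 (0.24). The autism genes (0.10) did with a pseudocount of 2, quantile scaling (0.09), the replicate block and the library-number run, and without Het replicate 3 (0.14) or CRISPRa replicate 3 (0.13). The striatal markers (0.35) did with the replicate block, the library-number run and genes at 1 read (1.18), and without Het replicate 3 (0.89) or CRISPRa replicate 2 (0.54). The inhibitory markers did with genes at 1 read (0.56) and without Het replicate 3 (0.33) or CRISPRa replicate 2 (0.25), and the hippocampal and thalamic markers with the mitochondrial mean (-0.38) and without Het replicates 1 (-0.12) or 2 (-0.15). The microglia markers did with the mitochondrial mean (0.59) and without Het replicate 1 (0.23), and the potassium channels (0.21) and presynaptic release genes (0.13) without CRISPRa replicate 3.

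The named genes that did not pass between Het CRISPRa and Het had values, above 0, of 1.34 for Islr, 0.86 for Impg2, 0.80 for the transcription factor gene Adnp, 0.53 for Nwd2 and 0.48 for Rabgap1l. Below 0 they were Semp2l1 (-2.41), Mir99ahg (-1.57), Ptchd4 (-1.56), Rpl15 (-0.97) and Igsf11 (-0.77). With the replicate block Rpl15, Igsf11, Adnp, Mir99ahg and Semp2l1 passed, and without Het replicate 3 Rpl15 (-1.12), Igsf11 (-0.88), Mir99ahg (-1.80) and Semp2l1 (-2.93) did. With the library-number run as a covariate these 4 and Ptchd4 passed, Ptchd4 also passed with a pseudocount of 2 (-0.95), and Mir99ahg passed with only the 6 libraries fitted. Among the sodium channels and neighbours other than Scn2a 0 passed, with values that included -0.49 for Grb14, 0.56 for Scn4b and 0.39 for Kcnh7.

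The comparison of Het CRISPRa with WT asks how far the injected mice differed from mice with both Scn2a copies. Scn2a was at 271.3 ± 17.7 CPM against 250.3 ± 18.8 CPM (SD, n = 3 each), a difference of 0.12 ± 0.11 and a ratio of 1.08 that did not pass (adjusted p = 1.00; exact two-sided permutation p = 0.3). It was 0.06 without WT replicate 1 and 0.06 without CRISPRa replicate 2, and neither passed. By limma Gm3020 was the only gene of 18967 to pass, 335 had an unadjusted p under 0.05, and with the filter at 2 CPM, a pseudocount of 0.1, the replicate block or any single library left out 0 passed. The authors' deposited table held 8 genes (1 higher, 7 lower), among them Egr1 (-0.83, adjusted p = 8.2e-07) and Arc (-0.62, adjusted p = 0.0434).

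The immediate early genes had the strongest camera test at the preset correlation between Het CRISPRa and WT. Of 19 values 17 were below 0, with a median of -0.36 (camera adjusted p = 5.9e-12, and adjusted p = 0.129 with an estimated correlation). None passed over all genes, and 6 fell adjusted over the list alone. Egr1 was at 45.9 ± 3.55 CPM in Het CRISPRa and 82.9 ± 8.60 CPM in WT (-0.84 ± 0.13; adjusted p = 0.176), and Arc, a regulator of synaptic receptor traffic, was at 93.7 ± 8.37 and 146 ± 24.6 CPM (-0.63 ± 0.17). Fos was at -0.73 and Dusp1 at -0.53. The interferon list had a median of 0.37 (17 of 18 above 0, 0 passing over all genes or adjusted over the list alone; adjusted p = 3.8e-08, and adjusted p = 0.253 with an estimated correlation), with H2-K1 at 0.68, Ifih1 at 0.62, Ifit2 at 0.61 and Rtp4 at 0.50. Its mean level was 3.0 in CRISPRa replicate 1, 2.30 and 2.43 in the other two, and 2.12 to 2.31 in WT, and without CRISPRa replicate 1 the list median was 0.12. The markers of hippocampal and thalamic neurons had a median of -0.46 (14 of 15 below 0, 0 passing over all genes or adjusted over the list alone; adjusted p = 2.5e-07, and adjusted p = 0.340 with an estimated correlation), with C1ql2 at -0.78, Zbtb20 at -0.60, Lct at -0.58 and Fibcd1 at -0.36. The mitochondrially encoded mRNAs had a median of -0.42 (12 of 13 below 0, 0 passing over all genes or adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.499 with an estimated correlation), with mt-Nd3 at -1.0, mt-Atp8 at -0.57, mt-Nd1 at -0.45 and mt-Cytb at -0.44. Their median was -0.27 without WT replicate 2 and -0.62 without WT replicate 3, and the call was kept. Here too carry-over into the nuclei cannot be told apart from a change of expression.

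**Figure D4:**
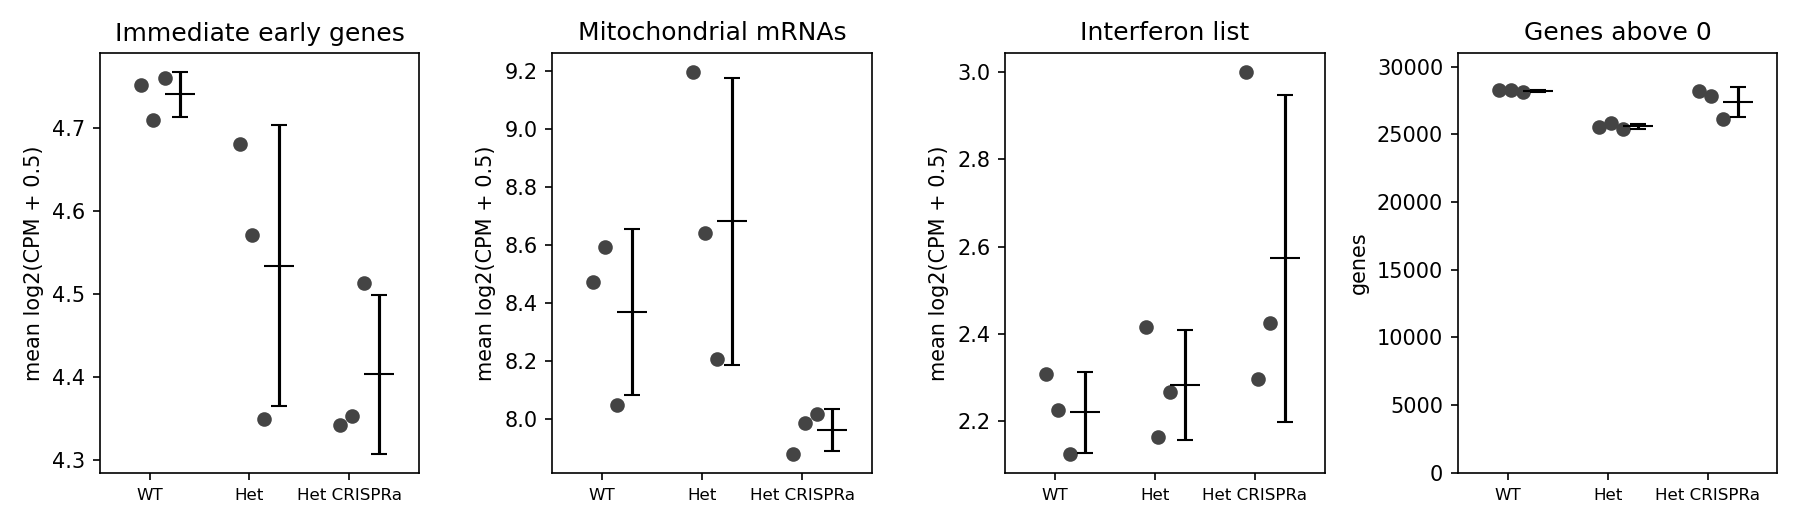
Mean log2(CPM + 0.5) of the immediate early genes, mitochondrially encoded mRNAs and interferon list (axes that do not start at 0) and the number of genes above 0 CPM, for each library of sorted cortical nuclei; the horizontal mark is the mean and the bars are the SD. CRISPRa replicate 1 stands apart in the interferon list (3.0), and the 3 Het libraries list fewer genes (25410 to 25801) than the 3 WT libraries (28109 to 28272).

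A further 4 lists passed between Het CRISPRa and WT, with 0 members passing over all genes or adjusted over the list alone. They were the ribosomal protein mRNAs (median -0.13, 26 of 28 below 0; adjusted p = 0.00103, and adjusted p = 0.818 with an estimated correlation; Rplp1 at -0.54), the heat shock proteins (-0.17, 9 of 11 below 0; 0.00624, and adjusted p = 0.499 with an estimated correlation; Hspa8 at -0.37 and Dnajb1 at -0.32), the markers of inhibitory neurons (-0.19, 16 of 19 below 0; 0.0318, and adjusted p = 0.818 with an estimated correlation; Slc32a1 at -0.50 and Sst at -0.34) and neuronal differentiation (-0.09, 13 of 18 below 0; 0.0353, and adjusted p = 0.499 with an estimated correlation; the neurofilament genes Nefl at -0.38 and Nefm at -0.35). Without WT replicate 2 none of these 4 calls was kept (ribosomal median -0.06, heat shock -0.07, inhibitory -0.20, differentiation -0.09). The ribosomal (-0.06), inhibitory (-0.19) and differentiation (-0.14) calls were also lost without WT replicate 1, the inhibitory call without CRISPRa replicate 2 (-0.01) and the differentiation call without CRISPRa replicate 3 (-0.04), and the ribosomal median turned to 0.09 with the mitochondrial mean as a covariate. Calls were kept at other medians without WT replicate 3 (ribosomal -0.26, inhibitory -0.09, differentiation -0.16), CRISPRa replicate 1 (inhibitory -0.30, differentiation -0.14) or CRISPRa replicate 3 (inhibitory -0.29), and the inhibitory median was -0.34 with the mitochondrial mean and -0.33 with genes at 1 read. The other 19 lists did not pass (adjusted p 0.164 to 0.978; medians -0.33 to 0.15). Of these, lists passed with the mitochondrial mean (striatal markers -0.96, microglia markers 0.35, sodium channels -0.15), genes at 1 read (striatal markers -0.31) and quantile scaling (presynaptic release -0.05). With single libraries left out, the vascular markers passed without WT replicate 1 (-0.42) or CRISPRa replicate 1 (-0.37), the microglia markers without WT replicate 2 (0.22), the excitatory postsynapse (0.06) and autism genes (0.05) without WT replicate 3, and the calcium channels without CRISPRa replicate 1 (0.07). Further named genes that did not pass were Rnf213 (1.10; 12.0 ± 6.76 against 4.79 ± 0.508 CPM), Il11ra3 (0.80), Impg2 (0.60), L3mbtl3 (0.40), Col24a1 (0.36), the calcium channel gene Itpr3 (-0.75) and the amyloid precursor gene App (-0.33). Among the sodium channels and neighbours other than Scn2a the values ran from -0.58 for Fign to 0.62 for Ifih1, with Scn4b at -0.43, and 0 passed. With the mitochondrial mean as a covariate, chosen after the results were seen, Scn4b (-1.32), Egr1 (-0.95) and Zbtb20 (-1.08) passed.

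Across the 18967 genes, the Het minus WT and the Het CRISPRa minus Het differences had a Pearson correlation of -0.704, and 76.4% of genes had opposite signs. Both differences contain the same Het libraries. Simulated data with no effect gave correlations with a mean of -0.521 (range -0.951 to 0.369), and 32 of 100 were at or below -0.704. In the authors' deposited tables all 11 genes higher in Het than in WT were lower in Het CRISPRa than in Het (0.0310 expected if the tables were independent, which the shared Het libraries exclude), and 1 of the 4 genes lower in Het was higher in Het CRISPRa. The Het libraries also listed fewer genes above 0 CPM than the WT libraries, at 25410 to 25801 against 28109 to 28272, while the Het CRISPRa libraries listed 28228, 27809 and 26118. Of the genes tested in both experiments (12528), 1913 passed in Neuro2a cells and 0 in the mouse comparison of Het CRISPRa with Het, so 0 were shared. In simulated data with 3 libraries against 3, 58 to 60% of genes changed 2-fold and 28 to 36% of those changed 1.5-fold were recovered.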

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

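The tests of the interferon list, of the 7 genes and of Gm3020 were chosen after these results were seen, with the bounds for the covariates, the TEC median and the sum of copies set before those values were seen, and the counts of splits were chosen before. In Neuro2a cells 1 of 100 splits of the 12 libraries, the real one, gave as many as 2166 genes, and the highest of the others gave 2. These splits treat the libraries as interchangeable, so they cannot exclude chance differences between batches of cultures that share a group and a set. The other splits also leave group and set differences in the residual spread, which holds their counts low. The split of library set 7 against set 8 gave 6179 genes, which points to a structure of the samples, and within the sets the CRISPRa comparison gave 6603 and 3505 genes. Among the 32 splits that part all pairs of libraries, the highest other gave 0. For the mouse comparisons the 10 possible splits are too few for a share under 0.05. The real counts there were 0 for Het against WT (10 of 10 splits as large, highest other 3), 8 for Het CRISPRa against Het (1 of 10, highest other 1) and 1 for Het CRISPRa against WT (5 of 10, highest other 2).

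In Neuro2a cells the interferon list was higher in CRISPRa cultures, with 26 of 29 members rising. The tables argue against the library set (median 0.71 within set 7 and 1.29 within set 8) and the per-million scaling (0.96 under median-of-ratios scaling) as the whole cause. They also argue against the amount of sadCas9-VP64 transcript as the whole cause, since in set 7 the CRISPRa cultures held less of it and their list mean was 0.91 ± 0.06 (SE) higher. A partial role of that amount stays open. In set 8 the CRISPRa cultures held more of it (599.8 against 349 CPM), and the list median was larger there. In both groups set 7 held more of it and had the higher list mean. The second plasmid and the total transgene load stay open: CRISPRa cultures of set 8 had a load of 2327 ± 214 CPM and a list mean 0.30 ± 0.07 above that of VP64-only cultures of set 7 at 2549.6 ± 83.7 CPM, but the second plasmid and the guide RNA came with the group and cannot be told apart. The response may thus follow from the added plasmid, from the guide RNA or from Scn2a itself, and no culture with another guide RNA was analysed here.

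In Het CRISPRa mice 7 unverified loci and pseudogenes were lower than in Het mice, with a median of -1.67 (SE 0.146 to 0.282). With genes at 1 read, a measure of library complexity, as a covariate the median was -1.79 (SE 0.224 to 0.379). With the mitochondrial mean it was -1.45 (SE 0.203 to 0.372). Of the 7 calls 0 and 1 were left, because the errors rose and, with the mitochondrial mean, the difference shrank. Neither covariate can be excluded as the cause, because the groups did not overlap in it and the fits extrapolate. Genes at 1 read numbered 1266 to 2045 in Het and 2095 to 2999 in Het CRISPRa libraries. The mitochondrial means were 8.21 to 9.19 and 7.88 to 8.02. The 609 other TEC loci had a median 0.0821 above that of protein-coding genes, which met the bound set against capture of such loci, but that bound was wrong, because 68 of them were lower and 33 higher at an unadjusted p under 0.05 (267 and 326 of 14091 protein-coding genes), and a median over loci that go both ways leaves capture of part of them open. The 7 genes stood at -0.85 to -0.21 in Het CRISPRa against WT, none passing, and their 0.88 to 1.86 in Het against WT is no independent evidence, since they were chosen on the same Het libraries. Something shared by the 3 Het libraries, or the genotype and its treatment, may also account for this, and the last was not tested.

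Gm3020 had reads in the 3 injected mice only, at a mean of 2.41 CPM. Its 33 listed near-identical copies summed to 116.0 ± 1.4 CPM in injected and 115.0 ± 8.6 CPM in other mice, a difference of 1.03 that is too uncertain against a spread of 8.6 to decide whether reads shared between paralogs moved. Of 39006 genes 1, Gm10409, was at 0 in all injected mice and at 1 CPM or more in all 6 others (1.12 to 5.01 CPM), as reads moved between Gm10409 and Gm3020 would need. Among the copies, Gm3194 (7.29 to 9.51 CPM) and Gm3383 (6.70 to 10.5 CPM) were also never above 0 in the same library. Which of them had reads varied within WT, Het and Het CRISPRa mice. Such one-or-the-other levels of copies thus also arose apart from the injection, though this pair was picked after its values were seen. The ratio of sadCas9-VP64 to Gm3020 was 2.24, 2.07 and 2.12 in the 3 injected mice, too few to test. That of Gm3020 to mCherry-puromycin varied more, at 1.73, 1.23 and 1.43. The Neuro2a table does not list Gm3020 (0 entries) at 318 to 2646 CPM of sadCas9-VP64, and it lists no feature at 0 in every library. If the missing entry means 0 reads, it goes against the sadCas9-VP64 transcript as the source, but the reason for its absence is not stated. Other parts of the virus stay open. Moved reads or the virus may thus explain the change, as hypotheses found and tested on the same data, and a biological difference at the locus was not tested.

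The change between CRISPRa and VP64 only differed between the library sets in 3132 of 14398 genes by a test of the difference. The log2 change was more positive in set 8 for 1357 of them and more negative for 1775. Of the 3132 genes, 208 passed in both sets with opposed signs. Transgene transcripts, which the gene tests left out, stood at 5.21 CPM (sadCas9-VP64) and 1.63 CPM (mCherry-puromycin) in Het CRISPRa mice and at 0 in the 6 others. In CRISPRa cultures they stood at 1977 and 5296 CPM in set 7 and at 599.8 and 1727 CPM in set 8. In VP64-only cultures sadCas9-VP64 stood at 2549.6 CPM in set 7 and 349 CPM in set 8. In 3 of 192 groups of values (1.56%), where chance gives about 1 in 20, a single library lay far from the others. The depth of VP64-only replicate 4 was 21 M reads, with a gap of 0.758 of the group's range. The heat shock list mean of CRISPRa replicate 3 lay 0.632 of the range from the nearest, and the Grb14 level of VP64-only replicate 2 lay 0.729 of the range away.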

How the results depend on the processing

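The covariates of mitochondrial mean and of genes at 1 read were chosen after the results were seen, and all other alternatives before. Genes at 1 read did not overlap between Het and either other mouse group. The mitochondrial mean did not overlap between Het CRISPRa and either other group. Fits of those comparisons with these covariates extrapolate and cannot separate group from covariate. In Neuro2a cells the count of genes past the threshold stayed within 1.5 times 2166 under the other pseudocounts, filters and scalings and ran from 1500 to 2411 with single libraries left out. It was 4513 with the replicate block, 5685 with the library set as a covariate, 6603 with set 7 alone and 3505 with set 8 alone, which remove the spread between the sets. The Scn2a change kept its direction and passed in every alternative but set 8 alone (0.47), where fewer samples were fitted.

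Between Het and WT the count was 2 with the replicate block, 1 with the library-number run, 2 with the mitochondrial mean, and 0 to 1 with single libraries left out. Between Het CRISPRa and Het it was 14 with a pseudocount of 2, 2 with no filter, 2 with the filter at 2 CPM, 31 with the replicate block, 31 with the library-number run, 0 with genes at 1 read, and 0 to 38 with single libraries left out. Between Het CRISPRa and WT it was 0 with a pseudocount of 0.1, the filter at 2 CPM, the replicate block or genes at 1 read, 10 with the mitochondrial mean, and 0 with any single library left out. For these the cause was not tested. With the mitochondrial mean the Scn2a difference between Het CRISPRa and WT was -0.0074 and that between Het CRISPRa and Het was 0.0264, and the cause was not tested. In no alternative did Scn2a pass in a mouse comparison.

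With the mitochondrial mean as a covariate several list medians reversed. These were the ribosomal protein mRNAs in Het against WT (-0.0946), Het CRISPRa against Het (0.154) and Het CRISPRa against WT (0.0921), and the immediate early genes in Het CRISPRa against Het (0.0764). With single libraries left out, the ribosomal median in Het against WT ran from -0.0536 to 0.223, and the inhibitory markers in Het CRISPRa against WT from -0.296 to -0.00967, where without CRISPRa replicate 2 the median and the camera test differed in sign. For these the cause was not tested. The correlation of the Het minus WT and Het CRISPRa minus Het differences ran from -0.830 to -0.520 with single libraries left out. The overlaps of called genes are fixed at 0 because 1 of the compared sets held 0 genes, so they say nothing of stability.

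Of the values of named genes under the alternatives, 1417 of 1467 in Neuro2a, 989 of 1022 in Het against WT, 763 of 824 in Het CRISPRa against Het and 1075 of 1111 in Het CRISPRa against WT kept direction and side of the threshold. For lists these numbers were 602 of 674, 439 of 538, 454 of 538 and 453 of 538. Calls gained (12, 19, 29 and 11 of these values) are given with each comparison. Beside the losses given with each list, fry kept none of the mouse list calls and not the Neuro2a ribosomal call. Other calls lost were presynaptic release and potassium channels (Het against WT) and neuronal differentiation (Het CRISPRa against WT) with median-of-ratios scaling, potassium channels (Het against WT) with a pseudocount of 0.1, and heat shock, inhibitory markers and differentiation (Het CRISPRa against WT) with no filter. With the mitochondrial mean, inhibitory markers and potassium channels (Het against WT) and heat shock and differentiation (Het CRISPRa against WT) were lost, and with genes at 1 read immediate early genes (Het CRISPRa against Het) and ribosomal mRNAs and differentiation (Het CRISPRa against WT). DESeq2 and edgeR on reads were not run, because whole reads could not be recovered. Sex as a covariate was not run, because all 9 mouse libraries held Xist at 3209 to 4066 CPM. The mouse libraries of the same number had correlations from -0.110 to 0.418 across genes, not all above 0.1, and were not treated as pairs. Replicate 3 of each mouse group has a library number of 15 to 17 and the others 7 to 12, and the highest correlation was that of Het and WT replicate 3, so the block overlaps the run of library numbers. At 3 libraries against 3, the simulated recovery of 28 to 36% at 1.5-fold limits what the mouse counts can show.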

Other observations

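The hypoxia list was written after the largest falls had been seen and before its own test, and its members already seen were left out of that test. In Neuro2a CRISPRa cultures, genes of the response to low oxygen were lower than in VP64-only cultures. Of 36 measured members not already seen (of 39), 20 fell and 0 rose, 33 values lay below 0 and the median was -0.56 (camera p = 3.0e-17, and p = 0.0467 with an estimated correlation). These p-values are not adjusted over lists, and with an estimated correlation the immediate early genes had an unadjusted p of 0.0170 and an adjusted p of 0.257, so the hypoxia list does not stand out by that test. P4ha2, a collagen prolyl hydroxylase, fell from 313 to 168 CPM (-0.90 ± 0.10, SE, n = 6 and 6). The glycolytic genes Pgk1 (-0.77 ± 0.19), Ldha (-0.57 ± 0.10) and Gapdh (-0.47 ± 0.09), the glucose transporter gene Slc2a3 (-0.75 ± 0.15), the oxygen sensor gene Egln1 (-0.72 ± 0.16), Plod2 (-0.77 ± 0.09), Ero1a (-0.77 ± 0.18) and Higd1a (-0.67 ± 0.09) fell as well. Ndrg1 (-1.34), Adm (-1.27), Slc2a1 (-0.52) and Vegfa (-0.25) did not pass. With all 44 measured members the median was -0.57, with 27 falling.

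The median of the members not already seen was -0.39 within library set 7 and -0.60 within set 8, so the library set alone does not account for it, and it was -0.62 under median-of-ratios scaling. These values are consistent with a hypoxia-response program that was less active in the CRISPRa cultures (median -0.56), a hypothesis found and tested on the same libraries. Culture density and oxygen were not analysed here, and a difference in either between the groups may give the same genes.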
